A study of Mus musculus with 34 samples.

How the data were processed

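Total RNA of mouse diaphragm and hindlimb was measured on 34 2-colour arrays: 18 of untreated mice and 16 of mice treated with L-arginine. The untreated and the treated arrays form separate value tables of different platforms, so every treated array lies in one table and every untreated array in the other. The labels place each array by tissue, strain (BL10 or mdx), treatment and age. Channel 1 is labelled with the strain at 12 weeks and channel 2 with the strain at the named age. The channel labels of treated arrays do not say if the 12-week RNA came from treated mice. The treated BL10 hindlimb array at 9 weeks names mdx in both channel labels; it was kept in the group of its title, and left out as an alternative.

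The deposited values were read as a linear ratio of the channels of each array, from the values themselves: column medians lie near 1, and some values are 0 or negative. The scanner, background correction, normalisation, scaling and dyes are not given in the sources used here. Scale, centring and direction of the ratio therefore stay unknown as stated facts. The direction was read as channel 2 over channel 1, the named sample over the 12-week RNA, and is called likely only. Untreated arrays of different strains correlated as low as -0.406 (Spearman rho over probes), and arrays of 1 strain, which share a reference label, no lower than -0.157; in the L-arginine table the lowest was -0.0996.

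The median deposited ratios at 3, 5, 9 and 12 weeks were 0.85, 1.01, 1.005 and 0.99 in untreated BL10 diaphragm, and 0.73, 1, 1.01 and 0.78 in untreated BL10 hindlimb. In untreated mdx diaphragm they were 1.08, 1.04 and 1.03 at 3, 5 and 9 weeks, 1.06 on Sample 1 and 1.01 on Sample 2. In untreated mdx hindlimb they were 1.015, 1 and 1 at those ages, 0.99 on Sample 1 and 1 on Sample 2. In treated mice they were 1.01, 0.95, 0.98 and 0.98 in BL10 diaphragm, 1.005, 0.99, 0.94 and 0.955 in mdx diaphragm, 0.96, 1.13, 0.98 and 1.04 in BL10 hindlimb, and 0.965, 1.22, 1.01 and 1.1 in mdx hindlimb.

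Each table held 1200 probes. By the platform annotation, 812 had 1 gene symbol, 99 had several (82 of them with an entry of the mitochondrial genome) and 289 were not listed. Genes were named only from probes with 1 symbol; of these, 793 untreated and 792 L-arginine probes had their gene identifier in the RefSeq gene table, and no symbol needed updating. Dmd, Nos1, Myh3, Myog, Col1a1 and Col3a1, fixed to be reported whatever their test, had no probe of that single name; Utrn had 1 probe and Igf2 had 3 per table. In the L-arginine table the Utrn probe had too few values for a test.

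Ratios were turned into log2, and values of 0 or below, 0 to 225 per untreated array and 2 to 36 per treated array, became missing. Probes with a value on at least 75% of the arrays of a table were tested: 1189 untreated and 1192 L-arginine probes. No further normalisation was made for the reported values. No 2 arrays held identical values, and the highest share of equal values of any pair was 2.58%. Probes of 1 sequence are those that the annotation lists under the same sequence entry, for entries with at most 20 probes. Whether such probes are identical was not checked. They agreed poorly on many arrays. Their Spearman rho ran from -0.068 to 0.425 (median 0.155) in the untreated table and 0.032 to 0.429 (median 0.236) in the L-arginine table. To check that the annotation belongs to the probes it is listed for, it was moved to each of the 1199 other positions along the table. The median rho over arrays was then at most 0.0844 untreated and 0.115 in the L-arginine table, below the real values at all positions. This check covers the annotation as a whole and not the gene name of a single probe. Neighbouring probes in the table's order were correlated, with a median rho of 0.284 and 0.355, and 0.136 and 0.216 once a running median over 51 neighbours was subtracted.

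Tests were made with limma 3.58.1 in R 4.3.3 (lmFit, eBayes, Benjamini-Hochberg at 0.05), with group and age as terms, and figures with Python 3.11.15. Ages were compared with 12 weeks and strains within each tissue and table. Interactions of strain and of tissue with age were fitted in each table and in both together. Treated and untreated arrays were compared over 632 genes with probes averaged per gene. The labels do not say that arrays came from separate animals, so p-values measure only the spread between these arrays, which may be technical. The other groups serve as replicates of each age, since each group had 1 array per age apart from Sample 1 and Sample 2.

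The design, the gene lists and the alternatives other than those named as added were fixed before the data were examined. Named genes are, for a comparison with calls, the 12 named probes with the smallest adjusted p in each direction and up to 6 further called list members; with fewer than 6 calls, the 6 with the smallest p are given as values that did not pass. Where a gene had several probes, the one with the smallest p is given. The text describes part of these genes. Of 21 gene lists, 14 had at least 5 measured members and were tested per gene with camera (preset correlation 0.01), camera with an estimated correlation, and fry, adjusted over the lists of a comparison, 280 tests in all. The lists for nitric oxide and arginine, adipocytes, blood cells, endothelium, nerve, smooth muscle with fibroblasts, and liver had too few members.

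The mean ratio to the 12-week RNA, the strain difference averaged over both tissues, the strain by tissue interaction and removal of the print-order trend were added after the planned comparisons had given few calls. With them, 46 counts of calls were computed, and the adjusted p-values are not corrected for that number. Alternatives were array centring, scaling to 1 median absolute deviation, quantile normalisation, other filters on missing values, robust eBayes, array weights, no age term, averaged Sample 1 and Sample 2 arrays, probes averaged per gene, and leaving out the 12-week arrays, the array with conflicting labels, each group and each array. Left out as alternatives chosen after seeing the data were the untreated BL10 hindlimb group, both Sample 1 arrays, both Sample 2 arrays, and the untreated BL10 hindlimb group with both Sample 2 arrays, the last chosen for poor agreement of probes of 1 sequence.

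The code was tested on simulated data with the residual spread of these arrays and 200 changed genes or probes, in 10 runs per comparison. Of changes of 2-fold and 4-fold, 66.1% and 91.7% were found for the strain difference in treated hindlimb (1192 probes), 48.2% and 86.8% for 3 against 12 weeks in the untreated table (1189 probes), 63.4% and 94.7% for L-arginine in mdx hindlimb (632 genes), and 1.2% and 19.4% for strain by age at 3 weeks in the untreated table (1189 probes). Of 14 simulated list shifts, camera found 14 for the strain difference in treated hindlimb (633 genes), with 4 calls of other lists. The simulated values were drawn independently for each gene or probe, unlike these arrays, where neighbouring probes correlated. With fewer than 200 changed, the adjusted threshold would also be harder to pass. These shares may therefore overstate what the arrays can show.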

Results

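Muscle RNA of mdx mice, which lack dystrophin, and of BL10 mice, which have it, was hybridised to 2-colour arrays with and without treatment with L-arginine, the amino acid from which nitric oxide synthases make nitric oxide. The 34 arrays formed 8 groups of 1 tissue (diaphragm or hindlimb), 1 strain and 1 treatment. Each group held 1 array at 3, 5, 9 and 12 weeks of age, 4 arrays in all. The untreated mdx groups of diaphragm and hindlimb held 5, since their labels number a Sample 1 and a Sample 2 at 12 weeks. Per the channel labels, channel 1 held a 12-week RNA of the strain and channel 2 the RNA of the named age. A value is therefore a ratio to a 12-week RNA and not an expression level, and a difference between strains is a difference between ratios to each strain's own RNA. The direction of the ratio is not given in the sources used here; it was read as the named sample over the 12-week RNA, which is likely from the order of the labels but not settled. With the ratio turned, every higher count below is a lower count and every lower count a higher one. The number of arrays limits the precision of every value.

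In hindlimb of L-arginine-treated mice, the macrophage genes Lyz2 and C1qb, and Sln, Postn and Igf2, had higher ratios in mdx than in BL10 mice. Lyz2, the lysozyme of macrophages, had a mean log2 ratio of 1.16 ± 0.24 (SD, n = 4) in mdx and -0.64 ± 0.29 (SD, n = 4) in BL10 hindlimb. C1qb, a complement component made by macrophages, had 1.60 ± 0.43 against -0.29 ± 0.68. Sln, sarcolipin, a regulator of the calcium pump of the sarcoplasmic reticulum, had 1.76 ± 0.56 against -0.05 ± 0.53. Postn, the matrix protein periostin, had 3.37 ± 0.76 against 1.08 ± 0.90, and Igf2, a growth factor of developing and regenerating muscle, had 3.21 ± 1.11 against 1.12 ± 1.12.

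This comparison asked how the strains differed under L-arginine. Of 1192 probes, 21 differed, 18 higher and 3 lower in mdx (limma, Benjamini-Hochberg), and 15 of them had 1 gene name. The differences of Sln (log2 1.81 ± 0.23 SE, adjusted p 0.00245), C1qb (1.90 ± 0.28, adjusted p 0.00624) and Lyz2 (1.81 ± 0.27, adjusted p 0.00624) came first among named genes. Ferritin light chain (Ftl1, 1.10) and the transferrin receptor (Tfrc, 0.94) were higher too, as were Lox, which cross-links collagen (1.59), Gpnmb (1.56), Tuba1a (0.95), Dync1i2 (0.67) and the 28S ribosomal RNA Rn28s1 (0.82). The other probe of Tfrc had means of 0.22 in mdx and 0.18 in BL10 hindlimb. The pyrophosphate transporter Ank (-1.17) and Arhgef7 (-0.92) were lower. Of 22 alternatives, the call held in 21 for Sln, in 20 for C1qb, Lyz2 and Ank, in 18 for Ftl1, 15 for Postn, 14 for Igf2 and 11 for Rn28s1. Most alternatives ended it for Lox, Tfrc and Arhgef7 (kept in 6 each), Gpnmb (5), Tuba1a (3) and Dync1i2 (1). For Lyz2, averaged over its probes, every mdx array lay above every BL10 array, from 1.00 to 1.62 against -1.16 to -0.17. The other probe of C1qb, of Postn, of Ank and of Arhgef7 pointed the other way, as did 1 of the 2 other probes of Igf2. The median over all genes of this difference was 0.13. Probes of 1 sequence agreed less on the BL10 than on the mdx array at every age of treated hindlimb. At 3, 5, 9 and 12 weeks their rho was 0.146, 0.219, 0.121 and 0.032 against 0.299, 0.407, 0.173 and 0.396. What this adds to the strain difference was not tested.

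Of the gene lists, inflammation and macrophage lay higher in mdx: 9 of its 11 measured members were positive, 5 passed adjusted over the list alone and 1 over all genes, on values averaged per gene. Its adjusted p was 0.0224 with camera and 0.314 with an estimated correlation. Collagen and matrix had 13 of 14 members above 0, with 1 past the test over the list alone and an adjusted camera p of 0.0819. Regeneration and development had 6 of 7 members above 0, 2 of them past the test over the list alone, with an adjusted camera p of 0.0879.

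The strain count depended on the scaling. Quantile normalisation left 0 calls (smallest adjusted p 0.0731), array centring gave 11 higher and 5 lower, removal of the print-order trend 25 higher and 29 lower, and the fit without the 12-week arrays 2. The treated BL10 hindlimb array at 9 weeks names mdx in both channel labels, and without it 12 probes differed, 9 higher and 3 lower. The count was 9 without the BL10 hindlimb array at 12 weeks or the mdx hindlimb array at 3 weeks, 12 without the mdx diaphragm array at 3 weeks, and 13 without the BL10 diaphragm array at 3 weeks or the mdx diaphragm or hindlimb array at 9 weeks.

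**Figure D1:**
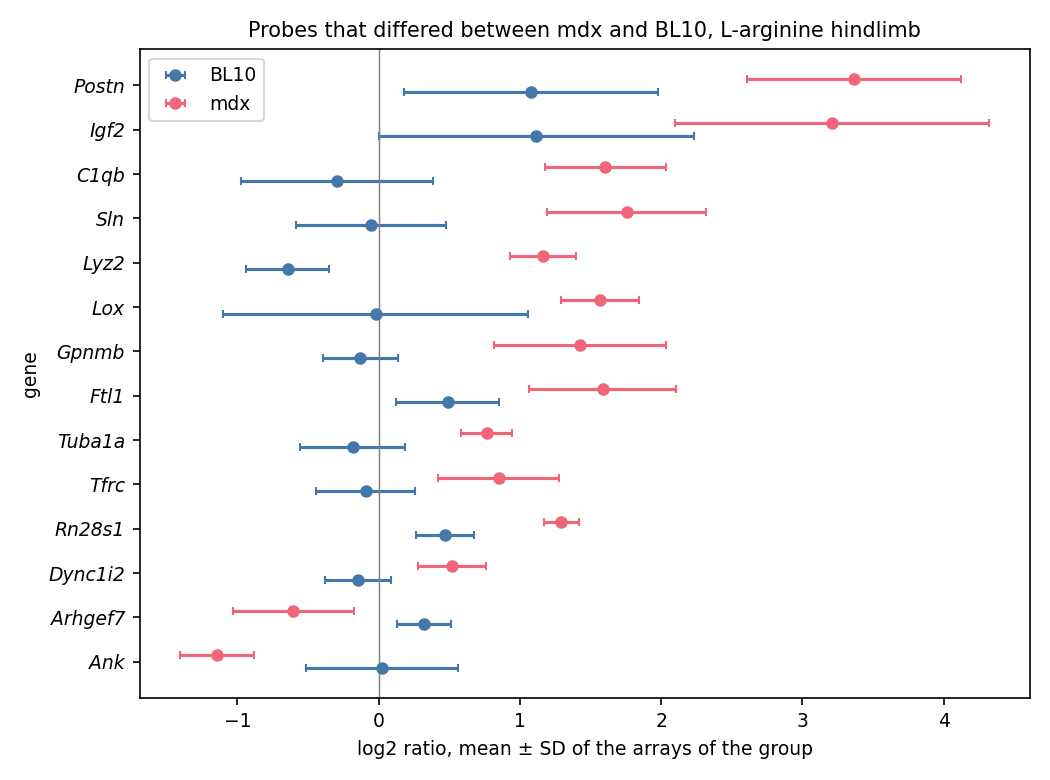
Mean log2 ratio with its SD over the 4 arrays of each group (x axis) for the named probes that differed between mdx and BL10 in L-arginine-treated hindlimb (y axis, gene). Postn and Igf2 had the highest mdx means, 3.37 and 3.21, while Ank and Arhgef7 lay below BL10.

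In diaphragm of L-arginine-treated mice the same direction was measured for Igf2 (2.36 ± 0.38 SE) and Postn (2.11). The other direction was measured for the desaturase Scd1 (-1.38, with 1 of its 2 other probes pointing the other way). No single probe passed. Limma made 0 calls, with 39 probes at an unadjusted p under 0.05; Igf2 and Scd1 had the smallest adjusted p, 0.0548. Without the BL10 hindlimb array at 9 weeks or the mdx diaphragm array at 3 weeks there were 2 calls, and without the BL10 hindlimb array at 3 weeks 1. The regeneration and development list, tested on values averaged per gene, lay higher in mdx, with 6 of 7 members above 0. Of its members 1 passed adjusted over the list alone and 1 over all genes, unlike the 0 calls over single probes. The list had an adjusted camera p of 0.0363, and the adjusted p was 0.358 with an estimated correlation.

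Whether the strain difference itself differed between the tissues, and what it was on average over both, were comparisons added after the planned ones had given few calls. The strain difference was not shown to depend on tissue under L-arginine: limma made 0 calls with 93 probes at an unadjusted p under 0.05, and Sln, first by p, differed by 1.52 in hindlimb minus diaphragm (adjusted p 0.297). Without the BL10 hindlimb array at 5 weeks there was 1 call. Averaged over both tissues, 23 probes differed, 19 higher and 4 lower in mdx, led by Igf2 (2.23 ± 0.27 SE, adjusted p 0.00315), Postn (2.20), C1qb (1.41), Lyz2 (1.54) and Sln (1.05). The muscle stress gene Ankrd1 (2.30-fold) and the matrix proteoglycan Bgn (0.76) were higher, and Scd1 (-1.13) was lower, although its 2 other probes pointed the other way. The call of Bgn held in 3 of 20 alternatives, and those of Igf2, Postn, C1qb, Lyz2, Sln, Ankrd1 and Scd1 in 19. The count fell to 0 after quantile normalisation and to 15 without the mdx diaphragm array at 9 or at 12 weeks.

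In untreated mice, few probes passed the test for a strain difference in the ratios to each strain's own RNA. A difference in expression shared by both channels of an array cancels in its ratio. These values therefore do not show how alike expression was in the strains. In simulated data for these comparisons, 47.6% of 2-fold changes were found in diaphragm and 42.5% in hindlimb. Of the hindlimb probes, 139 had an unadjusted p under 0.05 (limma), where about 59 are expected by chance. In hindlimb 1 probe differed, Nfe2l1, a transcription factor of the proteasome and stress response, at -2.62 ± 0.38 (SE, adjusted p 0.011) in mdx against BL10. It had a value on only 2 of the BL10 hindlimb arrays, with a mean of 2.69 ± 0.33 (SD, n = 2), against -0.004 ± 0.72 (SD, n = 5) in mdx. Utrn, utrophin, the relative of dystrophin, differed by 0.10 ± 0.31 in diaphragm (adjusted p 0.960) and 0.11 ± 0.28 in hindlimb (adjusted p 0.917). The 3 probes of Igf2 differed in hindlimb by 0.49 to 0.96, with adjusted p from 0.634 to 0.805.

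Limma made 0 calls in untreated diaphragm, with 107 probes at an unadjusted p under 0.05. The hindlimb count was 0 without the BL10 hindlimb array at 12 weeks or the mdx hindlimb array at 9 weeks, and 5 without the BL10 hindlimb array at 9 weeks; quantile normalisation gave 1 higher and 4 lower. The added comparisons gave 0 calls in untreated mice, with 57 probes at an unadjusted p under 0.05 for strain by tissue and 166 for the mean of both tissues. The mean of both tissues had 1 call without the BL10 hindlimb array at 12 weeks or the mdx hindlimb Sample 2 array. Strain by tissue had 1 without that Sample 2 array, and untreated diaphragm had 1 without the BL10 hindlimb array at 12 weeks.

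**Figure D2:**
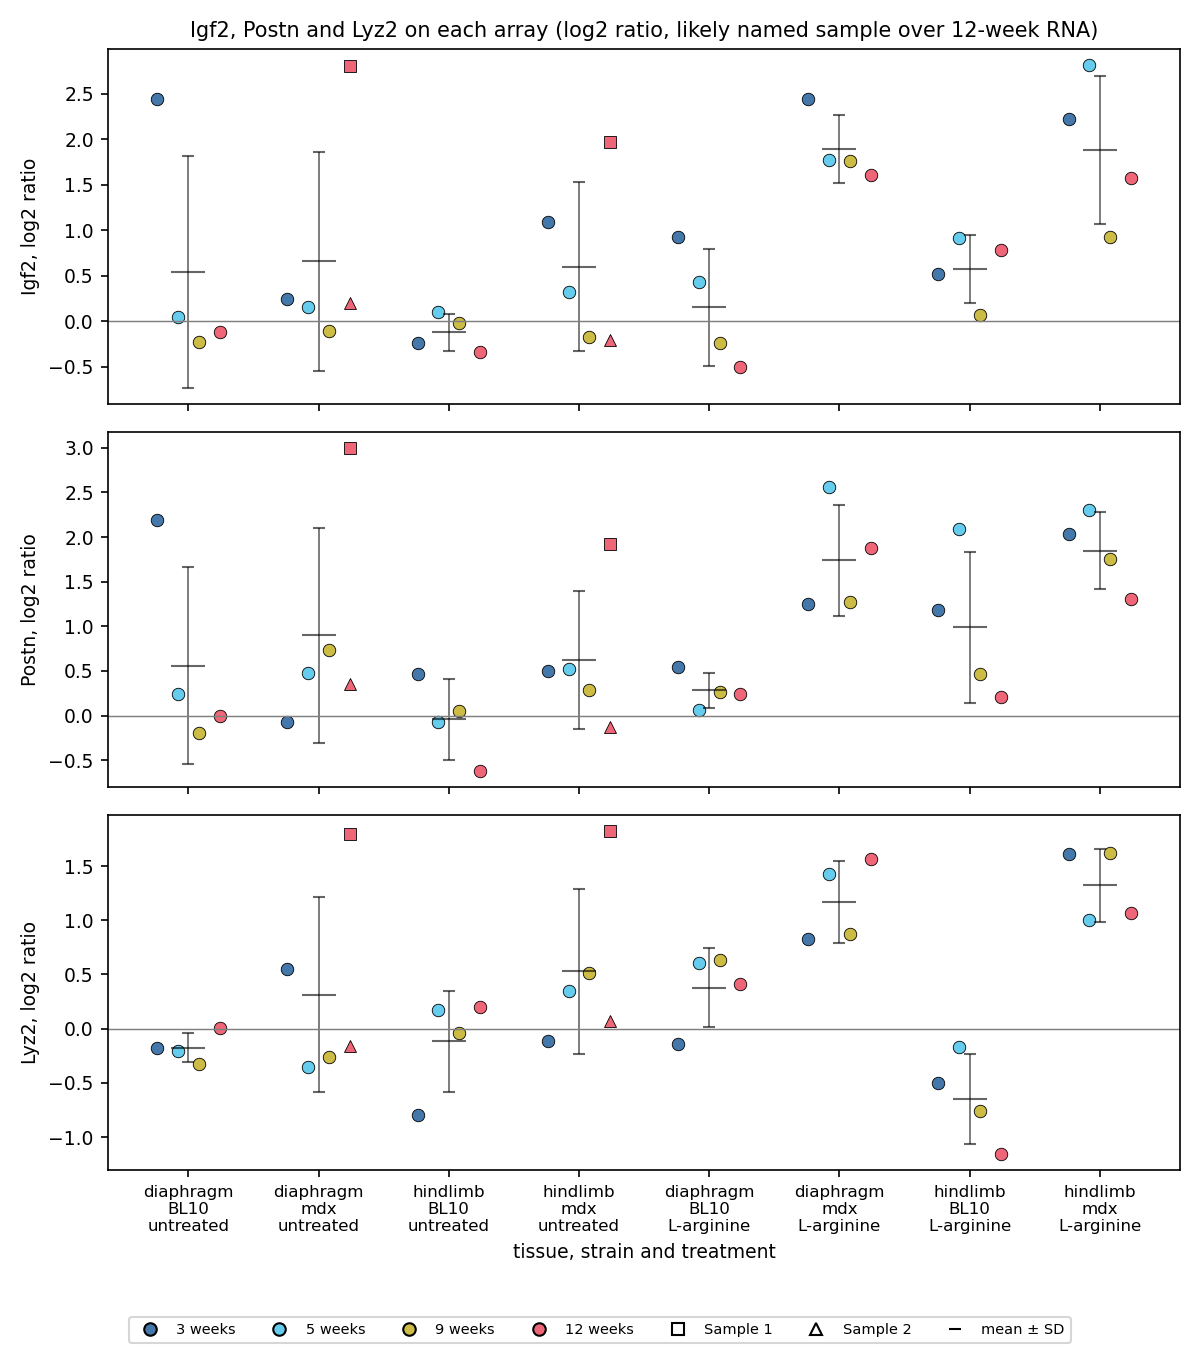
Log2 ratio of Igf2, Postn and Lyz2, averaged over each gene's probes (y axes), on every array, by tissue, strain and treatment (x axis), with age by colour, Sample 1 and Sample 2 by shape, and bars for mean and SD. On the untreated mdx arrays numbered Sample 1, Igf2 had 2.80 in diaphragm and 1.97 in hindlimb.

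L-arginine-treated and untreated arrays lie in separate tables of different platforms, so treatment and table cannot be told apart, and these differences are between tables. They were taken over the 632 genes named in both. In mdx hindlimb, the small matrix proteoglycan Fmod had a mean of 1.54 ± 0.94 (SD, n = 4) in the L-arginine table and 0.03 ± 0.27 (SD, n = 5) in the untreated one, and the collagen gene Col1a2 had 1.55 ± 0.77 against 0.26 ± 0.27. The ribosomal protein genes Rpl29 and Rpl3 were higher too (0.97 ± 0.61 against -0.11 ± 0.22 for Rpl29, and 0.96 ± 0.99 against -0.34 ± 0.66 for Rpl3). Tnni1, the slow-fibre troponin I, had 1.11 ± 0.56 against -0.06 ± 0.34.

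In mdx hindlimb 19 genes differed between the tables, 16 higher and 3 lower (limma). Fmod differed by 1.48 ± 0.29 (SE, adjusted p 0.0131), Col1a2 by 1.28 ± 0.29 (adjusted p 0.0177), Ssc5d by 1.78, the chaperone Pdia3 by 1.82 and Ftl1 by 1.12. Ndrg2 (-0.89), Ambra1, a regulator of autophagy (-0.71), and Psme3ip1 (2.29-fold) were lower. All 13 members of the ribosome and translation list were above 0, 7 past the test adjusted over the list alone and 2 over all genes, with an adjusted camera p of 0.00188 and an adjusted p of 0.268 with an estimated correlation. The median over all genes was 0.22.

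In BL10 hindlimb 27 genes differed, 21 higher and 6 lower. Probes of 1 sequence agreed little on the untreated BL10 hindlimb arrays. At 3, 5, 9 and 12 weeks their rho was 0.087, 0.079, 0.018 and 0.006, and the median ratio 0.73, 1, 1.01 and 0.78. What this adds to the difference was not tested. Higher were Fmod (1.77 ± 0.30 SE, adjusted p 0.000982), the cytochrome oxidase subunit Cox4i1 (2.03), the muscle thin-filament and light-chain genes Tpm3 (1.16), Tnni2 (1.17) and Mylpf (1.89, called in 15 of 45 alternatives), and Rplp0 (1.19). Lower were Nfe2l1 (-2.87, from 2 untreated BL10 hindlimb arrays with a value), the repair nuclease Ercc5 (-1.47), Bnip3l, which marks mitochondria for removal (-1.79), and the macrophage growth factor Csf1 (-1.66). In mdx diaphragm 4 genes were lower and 0 higher: the potassium channel genes Kcnj6 (-1.79 ± 0.33 SE, adjusted p 0.00894) and Kcnma1 (-1.76), the cytokine Il1b (-1.75) and Selenbp1 (-2.94). In BL10 diaphragm limma made 0 calls with 49 genes at an unadjusted p under 0.05, and Selenbp1 was first at -2.88 (adjusted p 0.0644).

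These splits moved with the scaling. After array centring, BL10 hindlimb had 7 higher and 6 lower and mdx hindlimb 6 higher and 4 lower. After scaling of the arrays, BL10 hindlimb had 12 higher and 6 lower, mdx hindlimb had 0 calls, and mdx diaphragm had 3 higher and 8 lower. After quantile normalisation, BL10 hindlimb had 9 higher and 6 lower, mdx hindlimb 0 higher and 2 lower, mdx diaphragm 5 higher and 4 lower, and BL10 diaphragm 14 higher and 5 lower.

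Single arrays moved these counts as well. The BL10 hindlimb count was 9, 54, 63 and 12 without the untreated BL10 hindlimb array at 3, 5, 9 and 12 weeks, and 17 without the treated one at 12 weeks. The mdx hindlimb count was 1 and 0 without the untreated mdx hindlimb array at 5 and 9 weeks, 4 without its Sample 2 array, and 9 and 6 without the treated mdx hindlimb array at 3 and 5 weeks. The mdx diaphragm count was 1, 2 and 1 without the untreated mdx diaphragm array at 3, 5 and 9 weeks, 23 without its Sample 1 array, and 8 and 0 without the treated mdx diaphragm array at 3 and 5 weeks. The BL10 diaphragm count was 1 without the untreated BL10 hindlimb array at 9 or 12 weeks, or the treated BL10 diaphragm or hindlimb array at 3 weeks.

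Differences of differences do not carry an additive difference between the tables that all groups share. They asked whether the difference between the tables differed with strain, tissue or age. A table difference particular to a strain, tissue or age, such as in its 12-week RNA, stays in them. They therefore do not set L-arginine apart from the table. By tissue, diaphragm minus hindlimb, 7 genes differed: Nfe2l1 was higher (1.36 ± 0.33 SE, resting on the same 2 untreated BL10 hindlimb arrays), and Fmod (-1.30), Ssc5d (-1.73), Phykpl (-1.66), Il1b (-1.50), the plasma protease inhibitor gene Serpina1a (-1.73) and Ftl1 (-1.02) were lower. The first 6 shared an adjusted p of 0.0397, and Ftl1 had 0.042. The fold differences of these 7 genes ran from 2.02 for Ftl1 to 3.32 for Ssc5d. Fewer than 1 in 2 alternatives kept each call, from 12 of 41 for Ftl1 to 19 of 41 for Fmod.

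The count by tissue was 1 higher and 0 lower after array centring, 1 higher and 2 lower after quantile normalisation, and 2 higher and 0 lower with the print-order trend removed. It was 16 without the untreated BL10 diaphragm array at 3 weeks, 11 without the treated BL10 hindlimb array at 9 weeks, and 18, 3 and 1 without the treated mdx hindlimb array at 3, 9 and 12 weeks. It was 0 without any one of 18 arrays. Of untreated arrays these were the BL10 diaphragm arrays at 5, 9 and 12 weeks, the mdx diaphragm arrays at 3 and 9 weeks and its Sample 2, the BL10 hindlimb arrays at 3 and 12 weeks, and the mdx hindlimb arrays at 5 and 9 weeks. Of treated arrays they were the BL10 diaphragm arrays at 9 and 12 weeks, the mdx diaphragm arrays at 5, 9 and 12 weeks, the BL10 hindlimb arrays at 3 and 5 weeks, and the mdx hindlimb array at 5 weeks.

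By strain, Nfe2l1 (1.49, adjusted p 0.0749, resting on those 2 arrays too) and Ercc5 (1.05, adjusted p 0.1) came first and Sln had 0.89; limma made 0 calls with 58 genes at an unadjusted p under 0.05. Without the untreated mdx diaphragm array at 5 weeks there were 3 calls, and without the untreated BL10 diaphragm array at 3 weeks, the treated mdx hindlimb array at 12 weeks or the untreated mdx hindlimb Sample 2 array there was 1. By age limma made 0 calls, with 22 genes at an unadjusted p under 0.05 over all ages and 40 at 3 weeks, and Igf2 differed at 3 weeks by 0.44 ± 0.73 (SE, adjusted p 0.934).

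Age was followed against the 12-week arrays within each table. In the L-arginine table at 5 weeks, 12 of the 14 members of the collagen and matrix list were above 0. The list median was 0.43 on values averaged per gene. A single probe of Col1a2 had 1.98 (adjusted p 0.222), and its other probe pointed the other way. The list had an adjusted camera p of 0.00794 and an adjusted p of 0.0713 with an estimated correlation; 0 members passed adjusted over the list alone and 0 over all genes. At 3 weeks, 1 probe of Igf2 had 1.25 ± 0.38 (SE, adjusted p 0.686) and Scd1 had -0.92 (adjusted p 0.527). In the untreated table, the albumin gene Alb had 1.69 at 5 weeks and 1.61 at 9 weeks, Gatm, an enzyme of creatine synthesis, had -0.97 and -0.84, and Acadl, an enzyme of fatty acid oxidation, had 1.09 at 3 weeks. None of these passed: the adjusted p was 0.946 at 5 weeks and 0.931 at 9 weeks for Alb and Gatm, and 0.459 for Acadl.

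Limma made 0 calls at every age, with 89, 34 and 36 untreated probes and 72, 110 and 33 L-arginine probes at an unadjusted p under 0.05 at 3, 5 and 9 weeks. With the 12-week arrays left out and each age set against 0, the L-arginine table gave 9, 3 and 4 calls. Without the untreated mdx hindlimb array at 3 weeks, the untreated table gave 8 calls at 3 weeks.

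The change with age was then compared between the strains. In the untreated table at 3 weeks, 10 probes were higher in mdx than in BL10 and 0 lower. They included Slc40a1, the iron exporter ferroportin (4.21 ± 0.63 SE, adjusted p 0.0136), Lpcat1, a lipid-remodelling enzyme (5.40 ± 0.93, adjusted p 0.0197), Nckap1, an actin regulator (3.55), and 1110003O08Rik (4.86, adjusted p 0.00421). The 3-week BL10 arrays had 168 non-positive values in diaphragm and 225 in hindlimb, the most of any arrays. For a probe with a gap on 1 of them, the BL10 side at 3 weeks rests on the other array alone. Slc40a1 had a value in 23 alternatives and Lpcat1 in 25, against 27 for Nckap1 and 1110003O08Rik. The oxidative phosphorylation list lay lower, with 5 of 18 members above 0, a median of -0.41, an adjusted camera p of 0.0349 and an adjusted p of 0.564 with an estimated correlation; 0 members passed adjusted over the list alone and 0 over all genes.

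The 3-week count was 0 after quantile normalisation and 2 over probes without missing values. It was 37 without the BL10 diaphragm array (35 higher, 2 lower) or the BL10 hindlimb array (37 higher, 0 lower) at 3 weeks. It was 36 without the mdx hindlimb array at 3 weeks. Without the BL10 diaphragm array at 12 weeks it was 23, with 12 higher and 11 lower, so the direction was not kept. It was 5 without the BL10 hindlimb array at 12 weeks and 0 without the mdx diaphragm array at 3 weeks. Over all ages 1 probe differed, 1110003O08Rik (adjusted p 0.00392), with 75 at an unadjusted p under 0.05. That count was 27 and 17 without the BL10 diaphragm array at 3 and 12 weeks, 18 without the BL10 hindlimb array and 7 without the mdx hindlimb array at 3 weeks, 3 without the mdx hindlimb array at 5 weeks or its Sample 2, 2 without the mdx diaphragm array at 5 weeks or the mdx hindlimb array at 9 weeks or its Sample 1, and 0 without the mdx diaphragm array at 3 weeks.

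Elsewhere limma made 0 calls for strain by age, at 5 and 9 weeks in the untreated table (43 and 48 probes at an unadjusted p under 0.05), over all ages and at 3, 5 and 9 weeks in the L-arginine table (9, 16, 18 and 15), and in both tables together (18, 43, 27 and 20 genes). Without the untreated BL10 diaphragm array at 12 weeks there were 27 and 19 calls at 5 and 9 weeks. For tissue by age limma made 0 calls over all ages and at 3 weeks: 52 and 112 untreated probes, 170 and 155 L-arginine probes and 38 and 58 genes of both tables had an unadjusted p under 0.05. For Utrn in the untreated table, the 3-week minus 12-week difference was 1.21 higher in diaphragm than in hindlimb, short of the threshold. Utrn had no value on the BL10 diaphragm array at 3 weeks, so its diaphragm side at 3 weeks was the mdx array alone (1.23). At 3 weeks the untreated count rose to 20, 28 and 29 without the BL10 diaphragm, mdx diaphragm and mdx hindlimb array of that age. The direction turned with the array left out: 19 higher and 1 lower, 0 higher and 28 lower, and 28 higher and 1 lower. The L-arginine count rose to 24 and 18 without the mdx hindlimb array at 3 and 12 weeks (19 higher and 5 lower, 17 higher and 1 lower).

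The mean ratio to the 12-week RNA, also added after the planned comparisons, differed from 0 for many genes of the L-arginine table. Ribosomal genes lay above 0, Rplp0 at 0.67 ± 0.10 (SE), Rps2 at 0.63, Rps26 at 0.44 and the ribosomal RNA Rn28s1 at 0.82, as did Igf2 at 1.89 ± 0.33, Postn at 1.82, Bgn at 0.79 and Tnni1 at 0.76. The glucose transporter Slc2a4 (-0.53), Pck1, an enzyme of glucose synthesis (-0.44), Selenbp1 (-1.73) and Mtpap (-1.17) lay below 0. All 13 members of the ribosome and translation list were above 0, 10 past the test adjusted over the list alone and 9 over all genes, with an adjusted camera p of 0.000637 and an adjusted p of 0.551 with an estimated correlation. In the untreated table the regeneration list had 6 of 7 members above 0 and the glycolysis list 1 of 9; both had an adjusted camera p of 0.0378, and the adjusted p was 0.633 with an estimated correlation. In these lists, adjusted over the list alone, 0 regeneration genes and 1 glycolysis gene passed, and 0 over all genes.

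Of 1192 probes, 357 lay away from 0 in the L-arginine table, 197 higher and 160 lower. By group the counts were 352 in mdx hindlimb (233 higher, 119 lower), 82 in mdx diaphragm (45 and 37), 18 in BL10 diaphragm (2 and 16) and 0 in BL10 hindlimb, where 252 probes had an unadjusted p under 0.05. In mdx hindlimb the split was 159 higher and 179 lower after centring, 177 and 192 with the print-order trend removed, and 59 and 85 after quantile normalisation; in BL10 diaphragm it was 48 and 37 after quantile normalisation and 4 and 10 with the trend removed. In the untreated table limma made 0 calls, with 85 probes at an unadjusted p under 0.05.

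Single arrays moved the group counts. The BL10 hindlimb count was 1, 5, 23 and 19 without its array at 3, 5, 9 and 12 weeks, and 3 and 7 without the mdx hindlimb array at 3 and 9 weeks. The BL10 diaphragm count was 4, 1 and 1 without its array at 5, 9 and 12 weeks, the mdx diaphragm count 50, 32, 43 and 41 without its array at 3, 5, 9 and 12 weeks, and the mdx hindlimb count 210 without its array at 5 weeks.

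At 12 weeks, untreated mdx muscle was hybridised on arrays numbered Sample 1 and Sample 2. Igf2 had 2.80 in diaphragm and 1.97 in hindlimb on Sample 1, against 0.21 and -0.21 on Sample 2, and Lyz2 had 1.79 and 1.82 against -0.16 and 0.07. Over all probes, Sample 1 and Sample 2 differed with an SD of 0.860 in diaphragm and 0.931 in hindlimb, where the median of the 153 untreated array pairs was 0.861. They were therefore kept as separate arrays. No p-value was computed for this description.

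**Figure D3:**
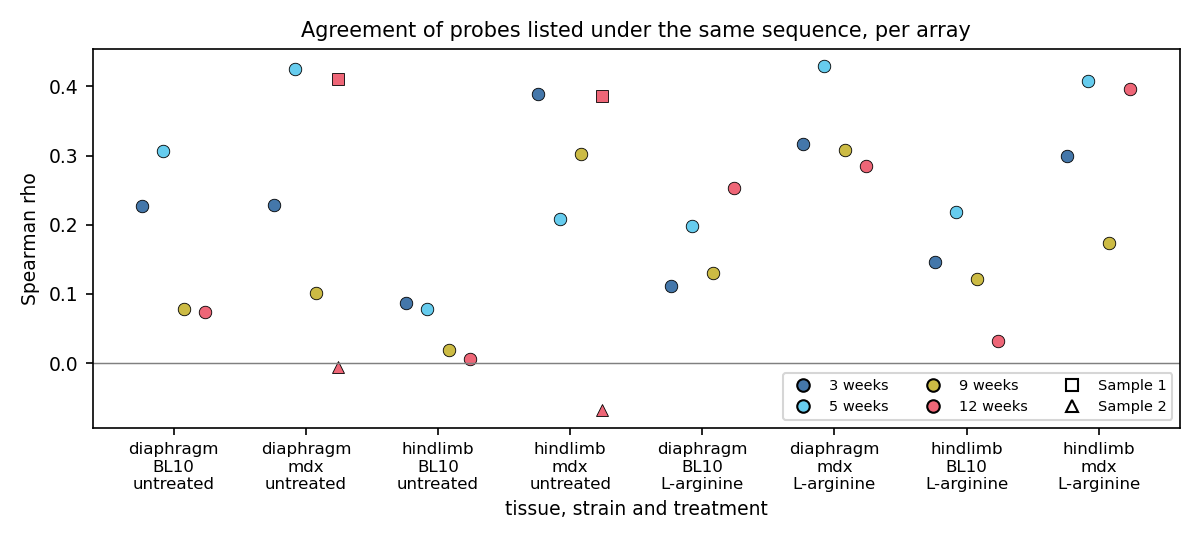
Spearman rho between probes of 1 sequence on each array (y axis), by group (x axis). It ranged from -0.068 to 0.425 in the untreated and from 0.032 to 0.429 in the L-arginine table.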

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

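All tests that weigh an explanation here, and all counts of other splits of the arrays, were chosen only after the result was seen; the interaction tests other than strain by tissue were planned.

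Of 43 groups of values tested for 1 array far from the others, 4 had one, and chance gives about 1 in 20. Igf2 had a log2 ratio of 2.80 on the untreated mdx diaphragm array at 12 weeks numbered Sample 1, where the other 4 lay between -0.10 and 0.25. Igf2 also had 2.44 on the untreated BL10 diaphragm array at 3 weeks, where the others lay between -0.23 and 0.05. That same BL10 array had a median ratio of 0.85 (the others 0.99 to 1.01) and 168 non-positive values (the others 0).

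Differences between groups came from interaction tests. The L-arginine difference between the tables differed between diaphragm and hindlimb for 7 genes, among them Fmod and Nfe2l1. The strain difference changed with age in the untreated table for 1 probe, 1110003O08Rik, over all ages, and for 10 probes, Slc40a1 and Lpcat1 among them, at 3 weeks against 12 weeks.

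On the Sample 1 arrays, Igf2, Postn and Lyz2 lay far above 0 although both channels are labelled 12-week mdx; the treated 12-week mdx arrays, with these labels too, had 1.61 and 1.57 for Igf2, 1.88 and 1.30 for Postn and 1.56 and 1.06 for Lyz2 (diaphragm, hindlimb), so the pattern is not one of Sample 1 alone. Across 632 genes these arrays correlated with the mdx minus BL10 difference of the L-arginine table (Spearman rho 0.2067; the bound set for it was 0.2), with 0.1812 and 0.2246 for the single arrays and -0.00834 for Sample 2. The treated mdx arrays behind that difference are labelled mdx in both channels too. The rho therefore cannot tell if channel 1 of Sample 1 held RNA other than 12-week mdx RNA. It passed the bound barely, and an untreated mdx hindlimb array at 3 weeks reached 0.2024. The rho of Sample 1 with the other untreated 12-week arrays was -0.008606. Over all probes this cannot decide on a dye or sequence bias common to them, since probes of 1 sequence agreed little on those other arrays. Their rho was 0.074 and 0.006 in BL10 diaphragm and hindlimb, and -0.006 and -0.068 on Sample 2. On those other arrays Igf2 had -0.33 to 0.21, Postn -0.62 to 0.35 and Lyz2 -0.16 to 0.20. On Sample 1 of diaphragm and hindlimb they had 2.80 and 1.97, 3.00 and 1.92, and 1.79 and 1.82. For these genes the values argue against a bias common to all untreated 12-week arrays. Different animals or degrees of muscle damage may explain the high values on Sample 1 as well and were not tested. No test asked why the treated 12-week arrays share them.

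Under L-arginine, 357 probes, those of Igf2, Postn and ribosomal genes among them, lay away from 0 on average. With a running median over 51 neighbours subtracted, 368 probes lay away from 0, 277 of them shared. This argues against a print-order trend on that scale as the whole explanation. Neighbouring probes still had a median rho of 0.216 after it, so a layout effect on a shorter scale stays open. A bias shared by all arrays, such as dye or layout, would give equal sizes in both strains; the median of BL10 over mdx means was 0.6416, and 0.595 to 0.694 with each array left out. The range crosses the bound of 0.67 set first and lies below a looser bound of 0.8, so this stays open. L-arginine cannot be told apart from the table, since 0 tables hold both treated and untreated arrays, and age, which channel 2 differs in, may add to it.

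The treated BL10 hindlimb array at 9 weeks names mdx in both channel labels. Its rho with the mdx minus BL10 difference of the other treated arrays was 0.05553, outside the 0.246 to 0.392 of the 8 mdx arrays. That difference is one between ratios to each strain's own RNA. An array of mdx RNA against RNA of another strain need not follow it, so the rho does not decide on that explanation. The treated mdx arrays are themselves labelled mdx in both channels. The rho lay below the lowest of them by more than their SD of 0.0597, the result set beforehand as against mdx RNA in both channels. It lay within the 0.038 to 0.333 of the 7 other BL10 arrays, a range that overlaps that of the mdx arrays. The rho thus does not separate the strains, and this does not decide on mdx RNA in both channels. Lyz2 had -0.76 on this array, against 1.00 to 1.62 on the treated mdx hindlimb arrays. Lyz2 was named from a comparison that counted this array as BL10, so its value is not independent of that. BL10 RNA under a wrong channel label stays open and was not tested further.

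Other splits of the arrays asked if a count of calls can come from chance. The shares are not corrected for the 40 results tested. Since groups hold 1 array per age, splits that keep the ages apart as the real one does were counted too. For the strain difference in treated hindlimb, with Lyz2 and Sln (21 probes), 1 of 35 splits, the real one, gave as many, and the highest other gave 3. For BL10 hindlimb between the tables (27 genes) it was 1 of 35, with a highest other of 9. In both, only 8 splits keep the ages, too few for a share under 0.05; the highest other of these gave 0 and 9.

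With the ages kept and each taken alone, 3 results had a share under 0.05. This does not exclude chance, since the shares are not corrected for the number of results and were counted after these were seen. The mean of both tissues under L-arginine, with Igf2 and Postn (23 probes), had 1 of 100 splits, with a highest other of 5, and 1 of 100 with a highest other of 4 with ages kept. Quantile normalisation left 0 calls for it. Between the tables, mdx hindlimb, with Fmod (19 genes), had 1 of 100 with a highest other of 7. With ages kept it had 1 of 24 (share 0.0417, the smallest these splits allow), with a highest other of 7. Its count was 0 after scaling, 2 after quantile normalisation, and 1 and 0 without the untreated mdx hindlimb array at 5 and 9 weeks. L-arginine by tissue (7 genes) had 1 of 100 with a highest other of 4, and 1 of 100 with a highest other of 2 with ages kept. Its other splits mix arrays of both tables within a group, so the difference between the tables widens their spread. A lower count in them therefore does not tell an interaction from that difference. The count by tissue was 0 without any one of 18 arrays, which the report names.

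For Nfe2l1 in untreated hindlimb (1 probe), 4 of 100 splits gave as many, with a highest other of 5, but with ages kept 3 of 24 did, so chance cannot be excluded. The call rests on 2 BL10 arrays, and the count is 0 without the BL10 hindlimb array at 12 weeks or the mdx hindlimb array at 9 weeks. Nor can chance be excluded for mdx diaphragm between the tables, with Kcnj6 and Il1b (4 genes; 5 of 100 splits, highest other 19; with ages kept 4 of 24, highest other 30), for strain by age at 3 weeks, with Slc40a1 (10 probes; 13 of 100, highest other 19), or over all ages (1 probe; 42 of 100, highest other 8). For the 31 results with 0 calls all 35 or all 100 splits gave at least as many by construction, which says nothing about chance. In 23 of these 31, some other split made calls.

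The highest other split of a result at 0 was as follows. For age against 12 weeks it was 13, 1 and 1 at 3, 5 and 9 weeks untreated, and 0, 1 and 5 treated. For strain it was 0 in untreated diaphragm, 0 for the untreated mean of both tissues, 7 in treated diaphragm, and 3 untreated and 5 treated for strain by tissue. For strain by age it was 2 and 2 at 5 and 9 weeks untreated, 1, 0, 2 and 0 treated (3, 5, 9 weeks, all ages), and 13, 0, 0 and 1 in both tables. For tissue by age it was 1 and 2 untreated, 11 and 48 treated, and 4 and 3 in both tables (3 weeks, all ages). For L-arginine it was 0 in BL10 diaphragm, 2 by strain, and 5 and 1 by age (3 weeks, all ages). These are the highest of 35 or 100 splits each, and no test asked what sets those splits apart. For mdx diaphragm between the tables, the highest others of 19 and 30 are several times the real 4, as a structure of the arrays beyond the compared groups would give, which was not tested.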

How the results depend on the processing

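Removal of the print-order trend and the leaving out of the untreated BL10 hindlimb group, of the Sample 1 arrays, of the Sample 2 arrays, and of that group with the Sample 2 arrays were chosen after seeing the data, as were the added comparisons (mean ratio, mean of both tissues, strain by tissue); the other alternatives were planned. Of 408 counts under alternatives, 330 stayed within 1.5 times the reported count and 78 moved. Of 2745 values of named genes, 2372 kept direction and side of the threshold, 313 fell short of it, 59 passed it anew and 1 reversed. For each moved value below, the cause was not tested.

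After array centring the count was 13 in BL10 and 10 in mdx hindlimb between the tables, 1 for L-arginine by strain, 1 by tissue and 2 for strain in untreated hindlimb. After scaling it was 11 in BL10 diaphragm, 11 in mdx diaphragm and 0 in mdx hindlimb between the tables. After quantile normalisation it was 19 in BL10 diaphragm, 9 in mdx diaphragm, 15 in BL10 hindlimb and 2 in mdx hindlimb between the tables, 2 and 3 for L-arginine by strain and by tissue, 1 and 5 for strain in untreated diaphragm and hindlimb, and 0 in treated hindlimb. It was 0 and 0 for strain by age untreated (all ages, 3 weeks), 2 for treated tissue by age over all ages, 8 and 0 for strain over both tissues untreated and treated, and 1 for untreated strain by tissue. The mean ratio gave 85 in BL10 diaphragm, 156 in mdx diaphragm, 3 in BL10 hindlimb and 144 in mdx hindlimb. Gene list calls, 8 with camera, were 5 after quantile normalisation, 19 with fry and 0 with an estimated correlation.

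With the print-order trend removed the count was 1 in BL10 diaphragm, 12 in BL10 hindlimb and 7 in mdx hindlimb between the tables, 1 and 2 for L-arginine by strain and by tissue, 54 for strain in treated hindlimb, 4 for untreated strain by age over all ages, 1 for untreated strain by tissue, and 54 for the mean ratio in BL10 hindlimb. Without an age term BL10 diaphragm between the tables had 1. Over probes without missing values, mdx diaphragm between the tables had 0 and strain by age at 3 weeks 2. With array weights, 3 weeks in the L-arginine table had 1.

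Without the 12-week arrays, which leaves fewer arrays, the ages of the L-arginine table tested against 0 gave 9, 3 and 4 at 3, 5 and 9 weeks. Gatm at 9 weeks in the untreated table turned to 0.019 (adjusted p 0.998). Between the tables the count was 14 in mdx diaphragm, 3 in BL10 hindlimb and 10 in mdx hindlimb, and for strain 1 in untreated diaphragm, 0 in untreated hindlimb and 2 in treated hindlimb. The mean ratio gave 193 over the L-arginine table, 0 and 31 in BL10 and mdx diaphragm, and 3 and 178 in BL10 and mdx hindlimb.

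Without the array with conflicting labels the count was 11 for L-arginine by tissue, 2 and 12 for strain in treated diaphragm and hindlimb, 1 for tissue by age at 3 weeks in both tables, and 23 for the mean ratio in BL10 hindlimb. Without the group of untreated mdx hindlimb, 3 weeks in the untreated table had 2. Without the untreated BL10 hindlimb group, BL10 diaphragm between the tables had 1, and untreated strain by age 4 (all ages) and 20 (3 weeks). Without the Sample 1 arrays, mdx diaphragm and hindlimb between the tables had 20 and 37. Without the Sample 2 arrays, mdx hindlimb between the tables had 4, L-arginine by strain 1 and by tissue 0, untreated strain by age 4 and 6 (all ages, 3 weeks), and untreated strain over both tissues and strain by tissue 1 each. Without that group and the Sample 2 arrays, mdx hindlimb had 11 and untreated strain by age 6 and 18.

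With each array left out in turn, 877 of 1016 counts stayed within 1.5 times and 139 moved. Here too a count of 0 that stayed at 0 was taken as unmoved, and many results were at 0, so counts with calls held less often. The lowest and highest were 0 and 8 for 3 weeks untreated; between the tables they were 0 and 1 in BL10 diaphragm, 0 and 23 in mdx diaphragm, 9 and 63 in BL10 hindlimb and 0 and 28 in mdx hindlimb. They were 0 and 3 for L-arginine by strain and 0 and 18 by tissue. For strain they were 0 and 1 (diaphragm) and 0 and 5 (hindlimb) untreated, and 0 and 2 and 9 and 28 treated. For untreated strain by age they were 0 and 27 over all ages, 0 and 37 at 3, 0 and 27 at 5 and 0 and 19 at 9 weeks; in the L-arginine table they were 0 and 1 for all ages and for each age, and in both tables they were 0 and 1 at 3 weeks. For tissue by age they were 0 and 18 (all ages) and 0 and 29 (3 weeks) untreated, 0 and 8 and 0 and 24 treated, and 0 and 1 at 3 weeks in both tables. For the mean ratio they were 282 and 360 over the L-arginine table, 1 and 26 and 32 and 109 in BL10 and mdx diaphragm, and 0 and 23 and 210 and 378 in BL10 and mdx hindlimb. For strain over both tissues they were 0 and 1 untreated and 15 and 27 treated, and for strain by tissue 0 and 1 in each.

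Of 7410 left-out values of named genes 6749 kept direction and side and 6 reversed, in strain by age and short of the threshold. C7 at 5 weeks untreated ranged from -3.50 to 0.35, the latter without the BL10 diaphragm array at 12 weeks. Prkar2a treated ranged from -1.95 to 4.05 at 3 weeks and from -1.28 to 4.43 at 5 weeks, lowest without the BL10 or the mdx diaphragm array at 12 weeks. Klhl18 at 3 weeks ranged from -0.031 to 3.11, lowest without the former.

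Signal over background is not given in the sources used here, so it cannot be set against these values. Probes of 1 sequence had a median rho of 0.155 untreated and 0.236 treated, which limits what a single probe shows, and up to 225 non-positive values per array became missing.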

Other observations

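The comparisons of probes of 1 sequence below, and the agreement of Sample 1 with Sample 2, were chosen after the values were seen; the gene lists and their tests were planned.

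The highest agreement of probes of 1 sequence was a Spearman rho of 0.425 in the untreated and 0.429 in the L-arginine table, and the lowest -0.068 and 0.032. On the untreated mdx arrays at 12 weeks it was 0.410 in diaphragm and 0.386 in hindlimb for Sample 1, and -0.00603 and -0.068 for Sample 2. Genes named from 1 probe, as Lox and Bgn are, have no other probe to check them. Sample 1 of diaphragm and Sample 1 of hindlimb had a rho of 0.405, while Sample 1 and Sample 2 had 0.074 in diaphragm and 0.016 in hindlimb. H19, an imprinted RNA of the Igf2 locus, had 1.52 and 2.82 on Sample 1 of diaphragm and hindlimb, and 0.41 and 0.01 on Sample 2.

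Of 280 gene list tests, camera made 8 calls, 0 of them with an estimated correlation, and fry made 19. The calls lay in the lists of regeneration (2), matrix, inflammation, glycolysis, oxidative phosphorylation and ribosome (2). The lists of the dystrophin complex, slow fibre, fast fibre, fatty acid use, proteolysis, calcium handling, cell cycle and stress had 0 camera calls. The nitric oxide and arginine list had 3 measured members, Gatm, Nos2 and Oat, too few for a test.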
